A study of Mus musculus with 18 samples.

How the data were processed

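RNA from the oviduct, uterus and vagina of newborn mice was hybridized to 18 Affymetrix arrays, 1 per sample. Of these, 17 are of the MOE430A type and 1, DES vagina array 1, is of the older MG_U74Av2 type. Per the file headers, the deposited per-array files give for each probe set a signal intensity on a linear scale, a detection call (Present, Marginal or Absent) and a detection p-value. The deposited value table holds the same intensity values, rounded, for every array but oil oviduct array 1. The software version and the scaling behind the authors' signal values are not given in the sources used here. The trimmed mean signal before scaling ranged from 26.5 to 143 over the 17 MOE430A arrays. It was 108 to 143 on the arrays numbered 3, which were scanned on a later day. On the others it was 59.8 to 79.3 in oviduct, 43.0 to 54.6 in uterus and 26.5 to 36.5 in vagina. Brightness before scaling thus went with the scan day and, on the first day, with the organ. The per-array file of oil oviduct array 1 repeats that of DES oviduct array 1, value for value, so its values came from the value table, which has no calls. Calls were therefore available for 16 of the 17 MOE430A arrays.

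Arrays were grouped by organ and treatment as the labels give them. The older-type array holds other probe sets and was in no fit. Signals were scaled so that the mean, after trimming 2% at each end, was 500 on each array, and log2(signal + 32) was taken. Of 22626 probe sets left without the 64 controls, 20380 carry 1 gene symbol, 691 several and 1555 none, and they cover 12393 genes. The 16702 probe sets called Present on at least 2 arrays were tested, for 9637 genes. A gene with several probe sets is represented by the one with the highest mean log2 signal.

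Each probe set was fitted with limma 3.58.1 in R 4.3.3 with 1 mean per group (11 residual and 5.81 prior degrees of freedom, variance trend). The contrasts were DES against oil in each organ and averaged over the organs, each pair of organs in oil and in DES, and the difference of the DES effect between organs. P-values were adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. They measure the spread between these samples, which per the labels came from 3 litters. Of 33 fixed gene lists, the 32 with at least 5 tested genes were tested with limma's camera, each list against all other genes tested. The preset correlation was 0.01, the tests were repeated with an estimated correlation, and p-values were adjusted over the lists within the contrast. Lists share members. Of the genes tested, 8 of 13 mesothelial, 12 of 36 estrogen-responsive uterine and 4 of 28 BMP pathway genes are also on another list. Shifts of such lists are not fully separate.

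Arrays with the same number in different groups were checked for pairing, by correlating their deviations from the group mean across genes. The median r was 0.284 (n = 40 pairs) for the same number and 0.233 (n = 25) for numbers 1 and 2 scanned on the same day. It was -0.351 (n = 55) across scan days. The scan day is thus a batch, which the ages in the array names would go with, and the numbers were not taken as pairs. A fit with the scan day as a block (8.88 prior degrees of freedom) and fits within the first scan day are given beside the counts.

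The genes named were chosen by a rule. For each contrast they are the 12 largest rises and 12 largest falls among genes past the threshold that were called Present on every array of the higher group with no overlap between groups, a set of fixed genes, and from each list up to 4 members past the threshold and 2 others. The named fixed genes were given whatever their result. The groups, contrasts, tests, gene lists, naming rule and most alternatives were set before the data were examined. A fold against a group called Absent on all its arrays with calls is a lower bound. Each array of that group counted with its own signal or its lowest Present signal, whichever was higher. Oil oviduct array 1, without calls, always counted with its own signal. Where every own signal was the higher, the bound equals the fitted fold. The procedure was tested on simulated data: with changes added to 200 probe sets, a log2 change of 1 was recovered for 48% in the oviduct, 44% in the uterus and 26% in the vagina. A log2 change of 2 was recovered for 94%, 86% and 80%.

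The alternatives tried were quantile normalization, other pseudocounts (1 and 100), other filters on calls, the value table as source and only the groups compared. Others were no variance trend, array weights, fixed blocks for replicate number or scan day, and a random block for treatment and replicate number together. Each array was also left out in turn. Alternatives added after the data were seen were the first scan day alone, leaving out 2 oviduct arrays with conflicting records, and leaving out 3 oil arrays with skeletal muscle transcripts.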

Results

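Gene expression was measured in the 3 organs that form along the Müllerian duct of the newborn female mouse: the oviduct, the uterus and the vagina. Their mothers had received diethylstilbestrol (DES), a synthetic estrogen, or oil. Per the labels, the dose was 67 µg per kg of maternal body weight, injected daily from fetal day 10 to 18. Per the labels, RNA was taken at birth from 3 litters. However, the analysis names of the arrays numbered 3 give 19 days post coitum, where those known for arrays 1 and 2 give 0 days after birth. Whether an array number marks a litter is not stated. The 18 arrays make 6 groups of organ and treatment with 3 arrays each. DES vagina array 1 was made on a different, older chip, so the DES vagina group has n = 2 in the comparisons of all arrays. Only 1 of these is from the first scan day, and within that day, or where either is left out, a lone DES vagina array is assumed to vary like the other groups. Among the 16 arrays with detection calls on the main chip, 52.7% to 66.3% of probe sets were called Present. The range was 52.7% to 58.6% on the first scan day and 63.7% to 66.3% on the second. Oil oviduct array 1 has no detection calls. Arrays 1 and 2 of each group were scanned on 1 day and array 3 on another, so any difference in age would go with the scan day. In the fits, the second day gave 1 of 2 DES vagina arrays but 1 of 3 arrays in every other group. Without a block, the scan day can thus enter the DES contrasts in vagina and on average. It can also enter the DES organ pairs and differences of the DES effect that involve vagina. The number of arrays limits the precision. Gene levels are mean scaled signal ± SD, the first-named group before the second, with n = 3 per group except DES vagina (n = 2). A value in parentheses alone is the log2 change from the limma fit. The words "at least" mark a fold against a group called Absent on all its arrays with calls.

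The first question is how the organs differ at birth without DES. The position of an organ along the duct goes with its set of Hox genes, which encode transcription factors that give regional identity. In oil, the oviduct exceeded the uterus in single Hoxc genes, with Hoxc4 (749 ± 293 against 71 ± 63.1, log2 change 3.02) and Hoxc8 (1120.4 ± 232 against 166 ± 50.5, log2 change 2.55). The oviduct was below the uterus in the AbdB-type genes Hoxa11 (308 ± 38.8 against 1682 ± 91.1, log2 change -2.34) and Hoxd10 (478 ± 69.9 against 1876 ± 62.3, log2 change -1.91). The same held for Hoxd9 (-1.46), Hoxd11 (-2.02) and Hoxa10 (-1.81). Hoxa10 lost this call when any of 3 arrays was left out (highest adjusted p = 0.0766, without oil uterus array 1). The vagina exceeded the uterus in Hoxd13 (5.6 ± 2.8 against 379 ± 15.9, at least 6.86-fold lower) and Hoxa13 (79.7 ± 46.2 against 288 ± 41.7, log2 change -1.58), given as uterus against vagina. Hoxa9, placed at the oviduct in the classical order, did not differ between oil oviduct and uterus (1653 ± 267 against 1841 ± 111, adjusted p = 0.849). It was higher in oviduct than in vagina (1653 ± 267 against 641 ± 86.9, adjusted p = 7.82e-05).

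**Figure D1:**
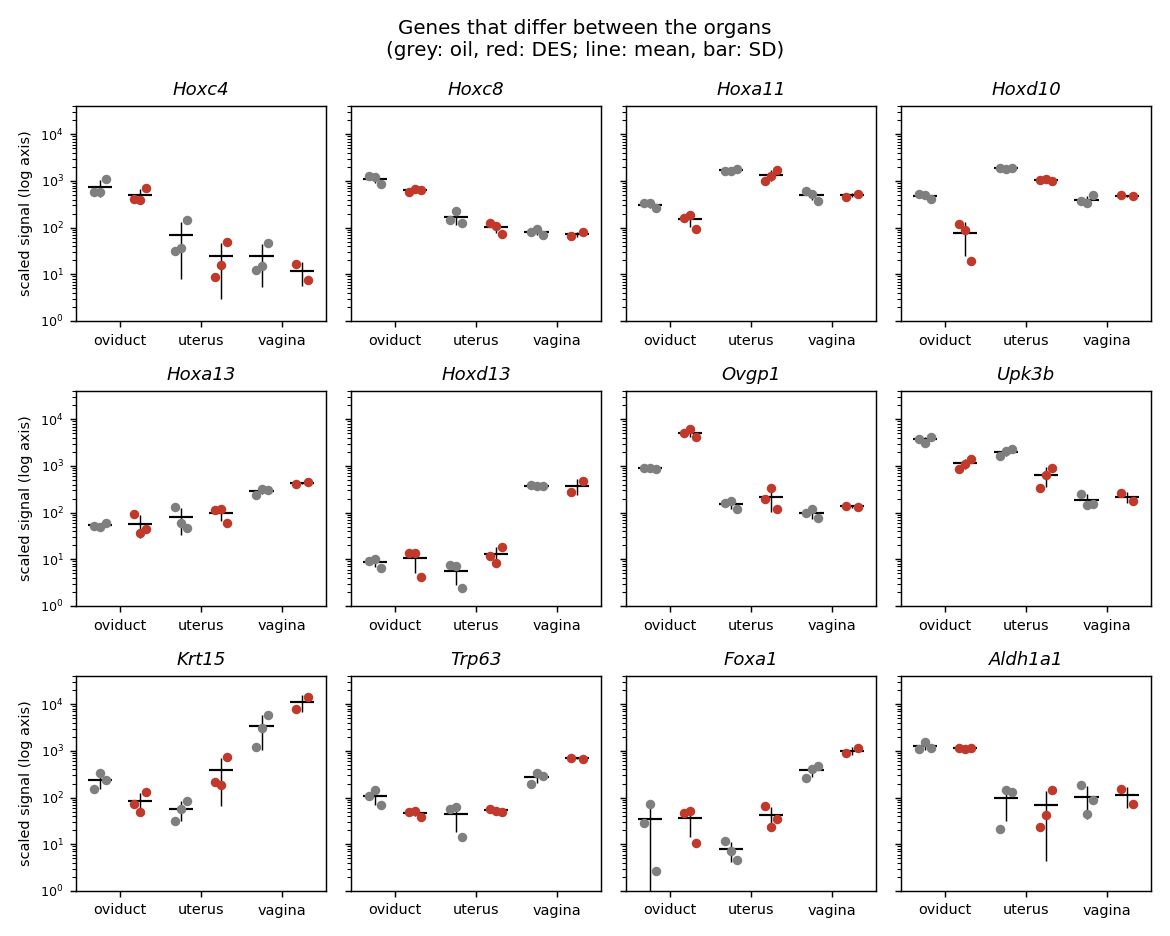
Scaled signal on a log axis for 12 genes in the 6 groups, 1 point per array, with the mean as a line and the SD as a bar (grey oil, red DES). Hoxc4 and Hoxc8 are highest in oviduct, Hoxa11 and Hoxd10 in uterus, and Hoxa13, Hoxd13, Krt15 and Trp63 in vagina.

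Other genes set the oil organs apart by tissue. The oviduct exceeded the uterus in Aldh1a1 (1272 ± 237 against 97.5 ± 66.3, log2 change 3.495) and Plet1 (2167 ± 375 against 189 ± 21.2, log2 change 3.31), and also in Ecrg4 (2.62) and Serpina3a (at least 7.44-fold). Aldh1a1 makes retinoic acid. The oviduct exceeded the vagina in Ovgp1, the oviduct-specific glycoprotein (900 ± 35.9 against 97.3 ± 22.7), and in the mesothelial gene Upk3b (3692 ± 503 against 184 ± 62.7). It did so too in the Wnt agonist Rspo1 (730.2 ± 86.3 against 55.4 ± 57.4). The uterus exceeded the oviduct in the homeobox gene Msx2 (215 ± 32.8 against 793 ± 64.7, at least 3.36-fold lower). The uterus also led in Cpxm2 (-2.08) and Prdm1 (-1.59). The vagina exceeded the uterus in basal and squamous keratins. Uterus against vagina gave Krt15 (56.9 ± 25.9 against 3445 ± 2406, at least 32.3-fold lower) and Krt5 (41.2 ± 34.7 against 917 ± 316, log2 change -3.73). The uterus was also lower in Krt4 (at least 18.4-fold) and Krt14 (at least 6.39-fold). The vagina led in Trp63, the master gene of stratified epithelium (45 ± 26.4 against 276 ± 73.9, adjusted p = 0.000526), and in Foxa1 (at least 6.76-fold) and Isl1 (at least 10.7-fold). It led in Dkk2, a secreted Wnt inhibitor (287 ± 50.1 against 1704 ± 451), and in Hdc, which makes histamine (45 ± 39.1 against 947 ± 325). Wnt4 was higher in uterus than in vagina (1235 ± 122 against 434 ± 118, adjusted p = 0.000144).

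Fixed gene lists showed the same split. The 11 anterior Hox genes were shifted to the oviduct side of the uterus (median log2 change 0.63, adjusted p = 3.73e-06). Of 11 posterior Hox genes, 5 were lower in oviduct than in uterus and 1 higher (median log2 change -0.32, adjusted p = 0.000242, adjusted p = 0.0625 with an estimated correlation). Of 23 stratified squamous genes, 14 were lower in uterus than in vagina (median log2 change -1.44, adjusted p = 3.11e-20). So were 12 of 23 simple epithelium genes (median log2 change -0.81, adjusted p = 3.18e-18). Markers of other tissues moved too. Of 21 neural and Schwann cell genes, 9 were lower in uterus than in vagina (median log2 change -1.22, adjusted p = 8.59e-16). Of 28 skeletal muscle genes, 7 were lower there (median log2 change -1.37, adjusted p = 2.66e-11, adjusted p = 0.0742 with an estimated correlation). Mesothelial genes were higher in oviduct than in vagina for 9 of 13 and lower for 1 (median log2 change 1.67, adjusted p = 1.31e-14). Macrophage and leukocyte genes were shifted to the oviduct side of the uterus (median log2 change 0.51, adjusted p = 3.88e-08). Of these, 3 of 26 passed the threshold, and 8 when adjusted over the list alone. Genes of ovary and oocyte were higher in oviduct than in uterus for 2 of 13 (median log2 change 0.91, adjusted p = 3.59e-06, adjusted p = 0.232 with an estimated correlation). These were Dppa3 (at least 6.42-fold) and Sycp3 (at least 5.21-fold). Neurofilament genes Nefm (2.84) and Nefl (2.497) went the same way.

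By limma over 16702 probe sets, the oil oviduct and uterus differed in 246 (169 higher in oviduct) and the oil uterus and vagina in 627 (231 higher in uterus). The oil oviduct and vagina differed in 659 (334 higher in oviduct). With the scan day as a block the counts were 772, 1363 and 1385, and within the first scan day alone 587, 965 and 958. Leaving out oil oviduct array 1 or 2, or oil uterus array 1 or 2, left 139, 161, 146 or 133 probe sets for oviduct against uterus. Without the 3 oil arrays with skeletal muscle transcripts, a choice made after the data were seen, the counts were 49 for oviduct against uterus, 466 for uterus against vagina and 263 for oviduct against vagina. That leaves 1 oil oviduct array, assumed to vary like the other groups. Leaving out oil uterus array 1 or 2 left 389 or 415 for uterus against vagina.

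In the oviduct, DES raised genes of motile cilia among others. The acute-phase gene Hp, which encodes haptoglobin, rose to 4990.2 ± 1792 against 49.3 ± 55 in oil (log2 change 6.097, adjusted p = 8.9e-08). Cilia genes called Absent in the oil oviduct appeared, with Rsph1 (2114 ± 616 against 84.6 ± 14.8, at least 18-fold higher) and Lrrc23 (2351 ± 97.4 against 161 ± 86.5, at least 13.2-fold higher). Also new were Tekt1 (at least 9.62-fold) and Meig1 (at least 7.67-fold). Rsph1 encodes a radial spoke protein and Tekt1 a filament of the axoneme. Strong rises came in Emb (5657 ± 200.4 against 210.1 ± 61.4, log2 change 4.59) and Bcat1 (4753 ± 870.2 against 180.4 ± 36.5, log2 change 4.49), and in Cbr2 (4063 ± 249 against 189 ± 64, log2 change 4.26) and Clca1 (1442 ± 683 against 32 ± 17.8, at least 18.4-fold higher). Emb encodes a cell-adhesion glycoprotein, Bcat1 a branched-chain aminotransferase, and Clca1 a secreted protein of mucous cells. The genes Ccna1 (at least 9.83-fold), Npy1r (at least 10.7-fold), Akr1c14 (3.52), Klf4 (2.55) and Lcn2 (2.48) rose as well. Of the fixed genes, the estrogen target Pgr (211 ± 62.2 against 39.6 ± 3.1, at least 3.32-fold higher, adjusted p = 0.000677) rose, and so did Dkk2 (979 ± 311 against 357 ± 97.9, log2 change 1.36, adjusted p = 0.00198). Ltf, which encodes lactoferrin, rose at least 2.35-fold (592 ± 165 against 229 ± 28, adjusted p = 0.00985), though not without DES array 3 (adjusted p = 0.0529). Foxa2 rose at least 2.43-fold (469 ± 47 against 182 ± 71.1, adjusted p = 0.0169). Its call was lost without any of 3 arrays (highest adjusted p = 0.0825, without oil array 3).

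The genes that fell in the DES oviduct include regulators of patterning. Wnt7a, which the duct epithelium needs for oviduct and uterus identity, fell from 372 ± 27.4 to 38.2 ± 35.6 (SD, n = 3 each). That is at least 6.18-fold lower (adjusted p = 0.000121). The Wnt inhibitor gene Nkd2 (170.2 ± 44.8 against 671 ± 67.5, log2 change -1.82, adjusted p = 0.000101) fell, and so did Wnt4 (439 ± 37.8 against 837 ± 119, log2 change -0.88, adjusted p = 0.00619). The Hox genes Hoxd10 (77 ± 52.5 against 478 ± 69.9, log2 change -2.36, adjusted p = 3.68e-05) and Hoxa11 (149.6 ± 48.8 against 308 ± 38.8, log2 change -0.94, adjusted p = 0.0155) fell. Hoxa11 lost its call without any of 3 arrays (highest adjusted p = 0.0778, without DES array 3). Among the largest falls were Gdf10 (111 ± 26.4 against 1376 ± 131, log2 change -3.31) and Crabp1 (125 ± 42.5 against 1163 ± 241, log2 change -2.95), with Moxd1 (-2.54) and Emilin3 (-2.32) beside them. Gdf10 encodes a BMP-family ligand and Crabp1 a retinoic acid binding protein. The single germ-cell genes Dppa3 (135 ± 5.9 against 1171 ± 781, log2 change -2.66) and also Sycp3 (at least 5.56-fold) and Tex15 (-2.405) fell. The fall of Tex15 was not limited to the oviduct, as it also passed as lower in uterus (fitted log2 change -2.09) and vagina (-1.29). The single neuronal genes Nefm (-2.89), Nefl (-2.55) and Stmn2 (-2.52) fell. The neural and Schwann list did not pass (median log2 change -0.21, adjusted p = 0.0891), though it did without oil oviduct array 3 (adjusted p = 0.0368). Falls were seen in the mast-cell genes Tpsb2 (at least 5.24-fold) and Cma1 (at least 3.77-fold) as well. Of the other fixed genes, Esr1 (-0.79), Hoxa9 (-0.48), Hoxa10 (-0.84), Hoxa13 (0.03) and Wnt5a (0.601) did not pass. Neither did Sfrp1 (-0.89), Pax8 (-0.07), Msx1 (-0.45) and Trp63 (-0.81). Of these, Hoxa10 (adjusted p = 0.00359), Wnt5a (adjusted p = 0.00960), Sfrp1 (adjusted p = 0.0287), Hoxa9 (adjusted p = 0.0300) and Trp63 (adjusted p = 0.0439) passed with the scan day as a block. Krt14 and Msx2 were called Absent in both oviduct groups. Pax2 and Emx2 have no annotated probe set and were not analysed here.

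By lists, 13 of 16 ciliated-cell genes rose in the DES oviduct (median log2 change 2.51, adjusted p = 2.07e-19), and 15 when adjusted over the list alone. Of 23 simple epithelium genes, 13 rose (median log2 change 0.86, adjusted p = 2.01e-12), for example Cldn7 (1.67) and Prom1 (1.57). Of 36 estrogen-responsive uterine genes, 12 rose and 4 fell (median log2 change 0.304, adjusted p = 0.000332), with Greb1 (366 ± 29 against 37.9 ± 12.3, at least 5.65-fold higher) up. Of 42 cell-cycle genes, 13 fell, and 27 when adjusted over the list alone (median log2 change -0.59, adjusted p = 2.74e-11, adjusted p = 0.0656 with an estimated correlation). Examples are Aurkb (-0.998) and Tk1 (-1.003). Of 40 Wnt pathway genes, 2 rose and 15 fell (median log2 change -0.62, adjusted p = 0.000187, adjusted p = 0.0708 with an estimated correlation), among them Dkk3 (1.92) and Nkd1 (-1.19). Posterior Hox genes fell for 4 of 11 (median log2 change -0.71, adjusted p = 0.00130, adjusted p = 0.0794 with an estimated correlation). BMP pathway genes fell for 5 of 28 and rose for 1 (median log2 change -0.46, adjusted p = 0.00106, adjusted p = 0.0794 with an estimated correlation). Imprinted genes fell for 5 of 19 (median log2 change -0.39, adjusted p = 0.000332, adjusted p = 0.0794 with an estimated correlation), for example Dlk1 (-1.11). Markers of other tissues fell beside these. They were 3 of 13 ovary and oocyte genes (median log2 change -0.998, adjusted p = 0.000124, adjusted p = 0.249 with an estimated correlation) and 4 of 13 mesothelial genes (median log2 change -0.71, adjusted p = 0.000678). Of 28 skeletal muscle genes, 1 fell and 1 rose (median log2 change -0.96, adjusted p = 0.00632, adjusted p = 0.452 with an estimated correlation, adjusted p = 0.0807 without oil oviduct array 3).

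Limma called 1300 probe sets in the oviduct, 733 higher and 567 lower with DES, for 516 and 394 genes. With the scan day as a block the count was 2560 with all 1300 among them, and it was 1746 within the first scan day. Without DES oviduct array 1 it was 817, the lowest when any 1 array was left out. Without the 3 oil arrays with skeletal muscle transcripts, a choice made after the data were seen, it was 463, 329 higher and 134 lower, with 1 oil oviduct array left.

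In the DES uterus, Clca1 rose from 111 ± 184 to 18716 ± 1576 (SD, n = 3 each, log2 change 7.91, adjusted p = 8.58e-07). So did Cbr2 (11348 ± 671 against 51.2 ± 45.2, log2 change 7.22) and Sprr2f (5760.2 ± 763 against 31.9 ± 15.2, log2 change 6.52). Rises were also seen in Arg1 (3818 ± 582 against 46.6 ± 29.1, at least 49.2-fold higher) and Agr2 (1998 ± 406 against 74 ± 105, log2 change 4.695), and in Prap1 (4.404), Padi1 (4.32), Lcn2 (4.29) and Serpinb11 (4.06). Sprr2f encodes a cornified-envelope protein that estrogen induces in the uterus, Agr2 a chaperone for mucins, and Arg1 arginase. The innate-defence gene Ltf rose at least 9.49-fold (1806 ± 579 against 168 ± 92.3), and the activin subunit gene Inhbb by 3.69 in log2 (1382 ± 125 against 77.5 ± 12). Smooth-muscle genes rose, with Pcp4 (2247 ± 263 against 143 ± 89.6, log2 change 3.87) and Myh11 (1444 ± 396 against 249 ± 37.2, log2 change 2.37) and Myl9 (0.99). The transcription factor genes Klf4 (2105 ± 214 against 171 ± 38.6, log2 change 3.41, adjusted p = 7.81e-09) and Foxa2 (590.2 ± 129 against 96.4 ± 54.6, log2 change 2.35, adjusted p = 0.000102) rose, and Elf3 (2.08) with them. Dkk2 (1137 ± 181 against 287 ± 50.1, log2 change 1.87, adjusted p = 0.000102) and Ngfr (2.39) rose too. Pgr (183 ± 56.9 against 74.9 ± 18.6, log2 change 0.98, adjusted p = 0.0391) rose in the fit of all arrays but not without any of 4 arrays (highest adjusted p = 0.160, without DES uterus array 1).

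Among the genes that fell in the DES uterus, Wnt7a went from 655 ± 37.9 to 81.7 ± 12.3 (SD, n = 3 each), at least 6.05-fold lower (adjusted p = 0.000126). The homeobox genes Msx1 (106 ± 95.7 against 571 ± 52.9, log2 change -2.42, adjusted p = 0.00238) and Msx2 (372 ± 83.1 against 793 ± 64.7, log2 change -1.05, adjusted p = 0.00153) fell. Msx factors act with Wnt signals between stroma and epithelium. Wnt-side genes Nkd2 (290 ± 112 against 1552 ± 115, log2 change -2.35, adjusted p = 7.01e-06) and Wnt4 (617 ± 99.9 against 1235 ± 122, log2 change -0.97, adjusted p = 0.00253) fell. Hoxd9 fell as well (853 ± 244 against 2037 ± 372, adjusted p = 0.00522). Amhr2, the receptor for anti-Müllerian hormone, fell at least 7.18-fold (15.6 ± 8 against 393 ± 136). Stra6, the retinol transporter, fell at least 6.17-fold (29.3 ± 16 against 385 ± 41.9). Further large falls were Cpxm2 (104 ± 33.9 against 1314 ± 30.6, log2 change -3.34) and Mmp10 (36.2 ± 24.6 against 622 ± 63.8, at least 9.83-fold lower), with Prdm1 (-2.44), Crabp1 (-2.23), Tnfrsf19 (-2.04) and Vcan (-1.93). Hoxa9 (-0.35), Hoxa10 (-0.55), Hoxa11 (-0.35), Hoxa13 (0.27) and Esr1 (-0.68) were not past the threshold. Nor were Wnt5a (0.61), Sfrp1 (-0.74), Pax8 (0.15) and Trp63, and Krt14 was called Absent in both uterine groups. Both Wnt5a (adjusted p = 0.00860) and Hoxa10 (adjusted p = 0.0481) passed with the scan day as a block.

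Estrogen-responsive uterine genes rose for 20 of 36 in the DES uterus and fell for 3 (median log2 change 0.84, adjusted p = 3.53e-11). Of 42 cell-cycle genes, 19 fell (median log2 change -0.62, adjusted p = 1.42e-13), 32 when adjusted over the list alone, among them Top2a (-0.86) and Cdk1 (-0.71). Smooth-muscle genes rose for 12 of 23 (median log2 change 0.62, adjusted p = 5.89e-09). Simple epithelium genes rose for 11 of 23 and fell for 2 (median log2 change 0.70, adjusted p = 6.47e-05). Stratified squamous genes rose for 8 of 23 (median log2 change 0.67, adjusted p = 6.47e-05, adjusted p = 0.102 with an estimated correlation), Krt5 (2.32) among them. Of 23 immediate early genes, 6 rose (median log2 change 0.22, adjusted p = 0.00319, adjusted p = 0.304 with an estimated correlation), for example Egr1 (1.63). Wnt pathway genes fell for 11 of 40 and rose for 3 (median log2 change -0.27, adjusted p = 0.0337, adjusted p = 0.279 with an estimated correlation, adjusted p = 0.0737 without oil uterus array 2). Stromal and matrix genes split, 12 up and 8 down of 31 (median log2 change 0.05, adjusted p = 0.0732), Lum (1.81) on the rising side. Their adjusted p was 0.0486 without DES uterus array 1 and 0.0179 without oil uterus array 3. Of the markers of other tissues, 1 of 28 skeletal muscle genes fell (median log2 change -0.72, adjusted p = 0.0337, adjusted p = 0.535 with an estimated correlation). That list's median was -0.01 within the first scan day and -1.51 within the second. Without oil uterus array 3 its adjusted p was 0.677, and without DES uterus array 3 it was 0.132.

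Limma called 1412 probe sets in the uterus, 802 higher and 610 lower with DES, for 541 and 410 genes. The count was 2676 with the scan day as a block, all 1412 among them, and 2075 within the first scan day. Leaving out DES uterus array 2 gave 933, and leaving out oil uterus array 1 gave 934.

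In the vagina, Sprr2f rose from 108 ± 54.7 (SD, n = 3) in oil to 6727 ± 1072 (SD, n = 2) with DES (log2 change 5.65, adjusted p = 1.7e-06). Further rises were Prap1 (1350 ± 1.5 against 24.5 ± 14.9, at least 22.4-fold higher) and Cbr2 (7132 ± 1038 against 488 ± 279, log2 change 3.905), with Ltf (2291 ± 266 against 170.4 ± 20.1, at least 11.5-fold higher) and Muc5b (978 ± 8.1 against 55.7 ± 35.9, at least 11.6-fold higher) beside them. Rises also came in Hp (at least 11.4-fold), Padi4 (at least 9.21-fold), Chad (at least 10.3-fold), Inhbb (3.56), Ecel1 (3.51) and Arg1 (3.43). Muc5b encodes a gel-forming mucin and Padi4 an enzyme that citrullinates proteins. Among squamous genes Krt13 (1785 ± 422 against 166 ± 187, log2 change 3.65, adjusted p = 0.00559) and Krt5 (4689 ± 724 against 917 ± 316, log2 change 2.37, adjusted p = 0.0114) rose. So did Krt14 (2484 ± 1180 against 498 ± 279, log2 change 2.31, adjusted p = 0.0327) and Calml3 (2.299). Without DES array 3 the adjusted p was 0.0854 for Krt13, 0.135 for Krt5 and 0.346 for Krt14. Trp63 was not past the threshold (689 ± 11 against 276 ± 73.9, adjusted p = 0.0642) in this fit but was with the scan day as a block (adjusted p = 0.0113). Wnt4 rose (1026 ± 104 against 434 ± 118, adjusted p = 0.00340), but not without DES array 3 (adjusted p = 0.0690).

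Hdc fell at least 17.3-fold in the DES vagina (13.8 ± 13.4 against 947 ± 325, adjusted p = 8.57e-06). Wnt7a fell at least 4.72-fold (81.4 ± 84.4 against 507 ± 106, adjusted p = 0.00197), but not without DES array 2 (adjusted p = 0.0649). Falls were also seen in Cldn6 (134 ± 37.4 against 745 ± 63.9, log2 change -2.24) and Cdh2 (199 ± 5.7 against 1026 ± 509, log2 change -2.07) and in Prom1 (1299.6 ± 191 against 5181 ± 698). The prostaglandin receptor gene Ptger3 (-2.12) and Cdh16 (at least 3.12-fold) fell too. Of the fixed genes, Nkd2 (261 ± 105 against 829.7 ± 98, log2 change -1.596, adjusted p = 0.00280) and Msx2 (352 ± 51.6 against 921 ± 134, log2 change -1.31, adjusted p = 0.00196) fell. Without DES array 3 their adjusted p was 0.0888 and 0.0525. Esr1, Pgr, Hoxa9, Hoxa10, Hoxa11, Hoxa13, Wnt5a, Dkk2, Sfrp1, Pax8, Msx1 and Foxa2 were not past the threshold, nor with the scan day as a block (lowest adjusted p = 0.0694, for Pax8).

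Stratified squamous genes rose in the DES vagina for 8 of 23 (median log2 change 1.26, adjusted p = 4.79e-15), and for 18 when adjusted over the list alone. Of 36 estrogen-responsive uterine genes, 11 rose and 1 fell (median log2 change 0.42, adjusted p = 4.69e-11). Of 42 cell-cycle genes, 3 fell (median log2 change -0.43, adjusted p = 2.04e-11, adjusted p = 0.101 with an estimated correlation). Of 25 endoplasmic reticulum stress and chaperone genes, 3 rose (median log2 change 0.46, adjusted p = 2.7e-06, adjusted p = 0.103 with an estimated correlation), for example the chaperone gene Hspa1b (1.27). Among other tissues, the 28 skeletal muscle genes shifted up with none past the threshold (median log2 change 0.904, adjusted p = 0.000615, adjusted p = 0.404 with an estimated correlation, adjusted p = 0.105 without oil vagina array 1). The neural and Schwann list shifted down, although its 1 gene past the threshold was up (median log2 change -0.53, adjusted p = 0.0159, adjusted p = 0.299 with an estimated correlation). Its adjusted p = 0.0612 without DES array 3 and 0.0946 without oil array 3.

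Limma called 359 probe sets in the vagina, 241 higher and 118 lower with DES, for 183 and 75 genes. The count was 880 with the scan day as a block, all 359 among them, and 649 within the first scan day, where the DES group is array 2 alone. It fell to 146 without DES vagina array 2 and to 162 without array 3, again with 1 DES array, and was 225 or 228 without oil vagina array 1 or 2. Of 61 named genes past the threshold, 28 stayed past it whichever array was left out.

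**Figure D2:**
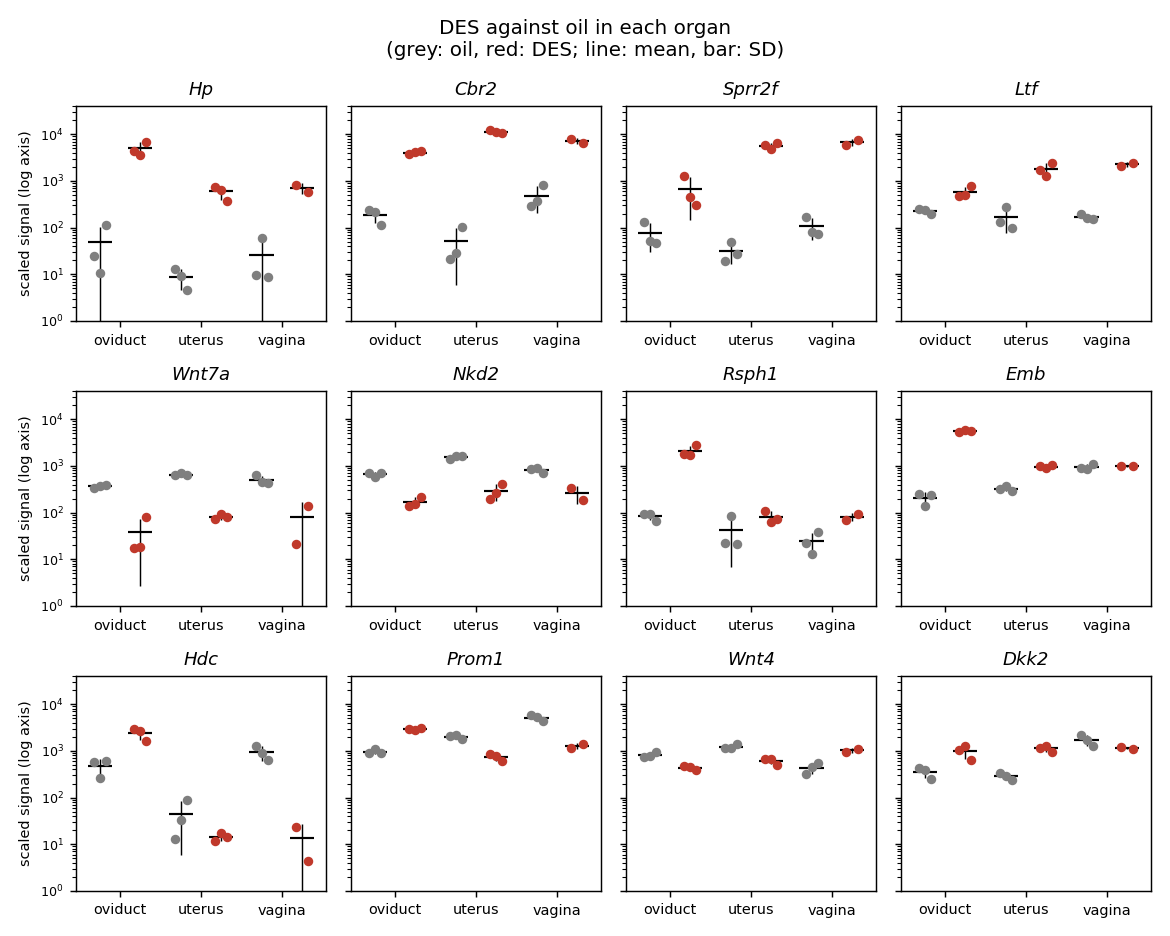
Scaled signal on a log axis for 12 genes in the 6 groups, 1 point per array, with the mean as a line and the SD as a bar (grey oil, red DES). Hp, Cbr2, Sprr2f and Ltf are higher and Wnt7a and Nkd2 lower with DES in every organ, while Rsph1 and Emb rise mainly in oviduct and Hdc, Prom1, Wnt4 and Dkk2 move differently between organs.

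Many changes were shared by the organs. Of 9637 genes, 84 were higher and 28 lower in all 3 organs. Averaged over the organs, rises included Cbr2 (5.13), Bcat1 (3.701), Akr1c14 (3.62), Serpinb11 (3.41) and Lcn2 (3.21). On average Sprr2f, Hp, Arg1, Prap1 and Padi1 rose too, but with an oil group called Absent in at least 1 organ. Falls included Cpxm2 (-1.95), Nkd2 (-1.92), Ptger3 (-1.85), Tnfrsf19 (-1.74), Prdm1 (-1.69), Emilin3 (-1.66), Limch1 (-1.45), Phgdh (-1.42) and Vcan (-1.26). Wnt7a and the mast-cell protease gene Cma1 were called Absent in every DES group. In oviduct, uterus and vagina, Wnt7a was lower by at least 6.18-fold, 6.05-fold and 4.72-fold, and Cma1 by at least 3.77-fold, 3.18-fold and 3.12-fold. Of the other fixed genes, Wnt5a (0.48) and Dkk2 (0.91) rose, as did Pgr (adjusted p = 0.000103) and Foxa2 (adjusted p = 0.000229), both Absent in oil oviduct. The rises of Dkk2 and Foxa2 did not hold in vagina, where neither passed. Their DES effects differed in the test between organs (adjusted p = 0.00512 and 0.0317). Msx1 (-1.12) fell, and so did Msx2 (adjusted p = 1.94e-05), which was called Absent in both oviduct groups. An averaged call need not hold in each organ: Wnt5a passed in no single organ, Msx1 in uterus alone, and Pgr not in vagina. Hoxa11 (-0.43), past in oviduct alone, and Sfrp1 (-0.68), past in no single organ, fell on average as well. Without DES vagina array 2 their adjusted p was 0.112 and 0.0673, and Hoxa11 lost its call without any of 12 arrays. Cell-cycle genes fell for 33 of 42 (median log2 change -0.58, adjusted p = 3.88e-16). Estrogen-responsive uterine genes rose for 22 of 36 and fell for 3 (median log2 change 0.68, adjusted p = 3.2e-09). Endoplasmic reticulum stress and chaperone genes rose for 11 of 25 (median log2 change 0.39, adjusted p = 1.18e-05, adjusted p = 0.0908 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose for 9 of 23 (median log2 change 0.304, adjusted p = 0.000614, adjusted p = 0.190 with an estimated correlation).

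The averaged contrast passed in 2860 probe sets, 1410 higher and 1450 lower, and in 4584 with the scan day as a block. With treatment and replicate number together as a random block it was 1496, 834 higher and 662 lower. Oviduct and uterus shared 216 rising and 179 falling genes, where independent lists of these sizes would share 29.0 and 16.8. Oviduct and vagina shared 89 and 33 (9.80 and 3.10), and uterus and vagina 145 and 50 (10.3 and 3.20). The organs share no oil array, but arrays of the same treatment and number were correlated across organs (0.373 in the fit with a random block). That fit has no term for the scan day, so the value takes in the scan-day batch and does not show pairing. The expectations for independent lists leave this correlation out. Genes are not independent replicates of each other.

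**Figure D3:**
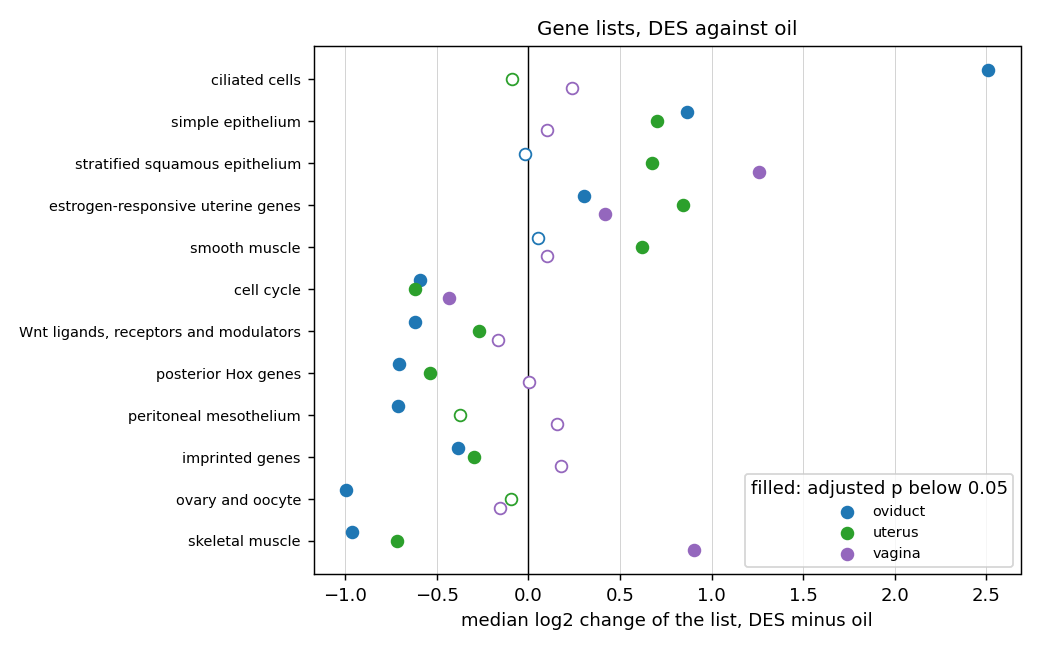
Median log2 change, DES minus oil, of 12 gene lists in oviduct, uterus and vagina, with filled points for lists whose adjusted p is below 0.05. The ciliated-cell list reaches 2.51 in oviduct, the squamous list 1.26 in vagina, and the cell-cycle list is below 0 in every organ.

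Whether DES acted differently in the organs was tested directly. Given as log2 changes in oviduct, uterus and vagina, clear differences were Emb (4.59, 1.48 and 0.07, adjusted p = 1.59e-07), Prom1 (1.57, -1.42 and -1.97, adjusted p = 1.59e-07) and Gdf10 (-3.31, -1.04 and 0.21, adjusted p = 3.33e-05). Others were Aldoc (1.99, 0.84 and -1.895, adjusted p = 7.18e-05), Cpxm2 (-0.76, -3.34 and -1.74, adjusted p = 0.000271) and Crabp1 (-2.95, -2.23 and -0.34, adjusted p = 0.000293). Hdc went in opposite directions, 2.296 in oviduct and at least 17.3-fold lower in vagina, while called Absent in uterus (adjusted p = 1.83e-05). Cilia genes changed most in oviduct, as in Rsph1 (at least 18-fold higher in oviduct, called Absent in uterus, called Absent in vagina, adjusted p = 0.000536) and Meig1 (at least 7.67-fold higher in oviduct, called Absent in uterus, called Absent in vagina, adjusted p = 0.000496). The smooth-muscle gene Myh11 (0.15, 2.37 and -0.25, adjusted p = 0.000494) and the T-box gene Tbx2 (0.10, -1.52 and 0.05, adjusted p = 0.00322) moved in uterus. Of single Wnt-related genes, Wnt4 (-0.88, -0.97 and 1.21, adjusted p = 0.000496), Dkk2 (1.36, 1.87 and -0.50, adjusted p = 0.00512), Dkk3 (1.92, 1.04 and -0.197, adjusted p = 0.000856) and Sfrp2 (-0.74, -0.62 and 1.06, adjusted p = 0.00292) differed. The Wnt list differed between vagina and oviduct (median log2 change 0.27, adjusted p = 0.0172, adjusted p = 0.196 with an estimated correlation), but not without DES vagina array 2 (adjusted p = 0.0588) or oil vagina array 3 (adjusted p = 0.134). The estrogen targets Ltf (at least 2.35-fold higher in oviduct, at least 9.49-fold higher in uterus, at least 11.5-fold higher in vagina, adjusted p = 0.00807) and Sprr2f (at least 5.85-fold higher in oviduct, 6.52 in uterus, 5.65 in vagina, adjusted p = 0.00219) passed as well, but their lower bounds do not rank the rises. Wnt7a (adjusted p = 1) and Nkd2 (adjusted p = 0.777) fell with no detected difference between organs. By lists, the DES effect on ciliated-cell genes was lower in uterus than in oviduct (median log2 change -2.71, adjusted p = 3.81e-23) and in vagina than in oviduct (median log2 change -2.28, adjusted p = 8.31e-21). The effect on simple epithelium genes was lower in vagina than in oviduct (median log2 change -0.86, adjusted p = 1.34e-12), and that on squamous genes higher (median log2 change 1.15, adjusted p = 1.14e-09). For smooth-muscle genes it was higher in uterus than in oviduct (median log2 change 0.65, adjusted p = 1.48e-08, adjusted p = 0.0550 with an estimated correlation).

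Limma's test for any difference in the DES effect passed in 297 probe sets for 224 genes, in 765 with the scan day as a block and in 430 within the first scan day, with 1 DES vagina array. Uterus and oviduct differed in 217 probe sets, vagina and oviduct in 227 and vagina and uterus in 37. The count over all organs was 181 without DES oviduct array 2 and 191 without oil oviduct array 1. Without the 3 oil arrays with skeletal muscle transcripts, a choice made after the data were seen, it was 99.

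Under DES, single Hox genes again differed between the organs. Oviduct against uterus gave Hoxa11 (149.6 ± 48.8 against 1344 ± 349, log2 change -2.93) and Hoxd10 (77 ± 52.5 against 1034 ± 54.4, log2 change -3.43), and further Hoxc4 (at least 7.61-fold) and Hoxa10 (-2.105). Uterus against vagina gave Hoxd9 (853 ± 244 against 204 ± 2.8, log2 change 1.88) and Hoxa13 (98.4 ± 32.4 against 432 ± 26.5, log2 change -1.86), and Hoxa13 lost its call without either of 2 arrays (highest adjusted p = 0.101, without DES vagina array 3). The list of posterior Hox genes was shifted for oviduct against uterus (median log2 change -0.55, adjusted p = 0.000436, adjusted p = 0.0450 with an estimated correlation) and for uterus against vagina (median log2 change 0.88, adjusted p = 0.00776, adjusted p = 0.111 with an estimated correlation, adjusted p = 0.104 without DES vagina array 2). It did not pass for oviduct against vagina (median log2 change -0.96, adjusted p = 0.0644), though it did without DES oviduct array 1 (adjusted p = 0.0214) or DES vagina array 2 (adjusted p = 0.0437). Anterior Hox genes were shifted to the oviduct side of the uterus (median log2 change 0.93, adjusted p = 2.4e-06) and of the vagina (median log2 change 1.31, adjusted p = 1.14e-07). They did not pass for uterus against vagina (median log2 change 0.24, adjusted p = 0.0751), though they did without DES uterus array 1 (adjusted p = 0.033). The DES oviduct led the DES uterus in Hdc (2391 ± 668 against 14.6 ± 2.7, at least 41.1-fold higher) and Ovgp1 (5136 ± 915 against 215 ± 109.7, log2 change 4.47), and in Rsph1 (at least 18.6-fold), Spa17 (3.64) and Agr3 (at least 8.02-fold). It trailed the DES uterus in Clca1 (1442 ± 683 against 18716 ± 1576, log2 change -3.804) and Sprr2f (688 ± 539 against 5760.2 ± 763, log2 change -3.25), and in Pcp4 (-3.24) and Chad (-2.898). Single keratins and squamous genes were higher in the DES vagina than in the DES uterus. Uterus against vagina gave Krt4 (89.3 ± 84.2 against 6491 ± 1947, at least 60.9-fold lower) and Krt15 (385 ± 318 against 11204 ± 4395, log2 change -4.95), with Krt14 (at least 26.6-fold), Ly6d (at least 27.2-fold), Psca (at least 19.9-fold) and Trp63 (-3.09). Skeletal muscle genes did the same, with Myh3 (12.6 ± 3.8 against 3264 ± 766, at least 56.7-fold lower) and Tnni1 (at least 22.2-fold). Oviduct against vagina under DES gave Ovgp1 (5136 ± 915 against 135 ± 9.1, log2 change 4.93) and Krt5 (47 ± 38.7 against 4689 ± 724, log2 change -6.003), and also Hdc (at least 43.2-fold) and Krt15 (at least 97.3-fold). Of 16 ciliated-cell genes, 11 were higher in DES oviduct than in DES uterus (median log2 change 2.83, adjusted p = 1.18e-22). Of 28 skeletal muscle genes, 19 were lower in DES uterus than in DES vagina (median log2 change -2.895, adjusted p = 7.34e-36). Of 23 smooth-muscle genes, 12 were lower in DES oviduct than in DES uterus and 1 higher (median log2 change -0.803, adjusted p = 1.17e-11).

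Limma called 703 probe sets for DES oviduct against uterus (468 higher in oviduct), 274 for uterus against vagina (64 higher in uterus) and 855 for oviduct against vagina (455 higher in oviduct). With the scan day as a block the counts were 1439, 534 and 1484. Within the first scan day they were 1059, 266 and 797, with 1 DES vagina array in the last 2 counts. For uterus against vagina 181 were left without DES uterus array 2, 108 without DES vagina array 2 and 105 without array 3. For oviduct against vagina 505 were left without DES vagina array 2 and 429 without array 3.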

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

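The tests of the ciliated-cell, oocyte and skeletal muscle patterns and of the other chip were chosen only after the results were seen. The tests of the DES effect between organs were planned.

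The DES effect differed between organs in 297 probe sets (F test over the interaction terms, limma). With adjusted p in parentheses, the genes named in the text whose DES effect differed between organs are Emb (1.59e-07), Prom1 (1.59e-07), Hdc (1.83e-05), Gdf10 (3.33e-05), Aldoc (7.18e-05), Cpxm2 (0.000271), Agr3 (0.000271), Crabp1 (0.000293), Myh11 (0.000494), Wnt4 (0.000496), Meig1 (0.000496), Rsph1 (0.000536), Ngfr (0.000559), Ecrg4 (0.000736), Dkk3 (0.000856), Inhbb (0.00131), Vcan (0.00131), Cbr2 (0.00186), Ccna1 (0.00190), Sprr2f (0.00219), Sfrp2 (0.00292), Lrrc23 (0.00315), Tbx2 (0.00322), Spa17 (0.00376), Tekt1 (0.00378), Dkk2 (0.00512), Ovgp1 (0.00512), Moxd1 (0.00537), Hoxd10 (0.00696), Pcp4 (0.00714), Bcat1 (0.00718), Ltf (0.00807), Egr1 (0.00857), Ddx4 (0.00869), Chad (0.0104), Tpsb2 (0.0113), Lyz2 (0.0129), Dppa3 (0.0139), Nefl (0.0181), Muc5b (0.0216), Amhr2 (0.0217), Padi4 (0.0282), Sycp3 (0.0305), Foxa2 (0.0317), Ecel1 (0.0337), Upk3b (0.0347), Krt15 (0.0348), Lcn2 (0.0352), Cldn6 (0.0371), Myl9 (0.0377) and Clca1 (0.0400). For Ltf, Tpsb2, Chad, Padi4 and Muc5b a group was called Absent in each organ, so their changes are lower bounds that cannot be ranked between organs. All 51 also passed with the scan day as a block. With that block 19 further genes named in the text passed, with adjusted p in parentheses: Cldn7 (0.00145), Krt5 (0.00199), Dlk1 (0.00507), Cd14 (0.00675), Trp63 (0.00758), Klf4 (0.00911), Nefm (0.00922), Krt14 (0.0114), Tnfrsf19 (0.0154), Prdm1 (0.0156), Elf3 (0.0180), Emilin3 (0.0188), Serpina3a (0.0219), Hp (0.0233), Myh3 (0.0320), Arg1 (0.0389), Hspa1b (0.0407), Plet1 (0.0429) and Tex15 (0.0488).

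Of 96 tests of a list's DES effect between organs, 37 passed with the preset correlation and 11 of these also with an estimated one. Between vagina and uterus this was the simple epithelium list (adjusted p = 1.14e-09). Between uterus and oviduct it was the ciliated-cell list (3.81e-23) and the estrogen-responsive uterine list (6.52e-05). Between vagina and oviduct the lists were ciliated cells (8.31e-21), simple epithelium (1.34e-12), stratified squamous epithelium (1.14e-09) and imprinted genes (7.53e-07). The BMP and TGF-beta pathway (0.00015), peritoneal mesothelium (0.00015), macrophage and leukocyte genes (0.000375) and the estrogen-responsive uterine list (0.0172) also differed there.

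The DES vagina array on the other chip was in no fit. Of 16 genes on both chips that rose in the DES vagina and were called Absent on all oil vagina arrays, 12 (75%) were called Present on it, among them Hp, Ltf, Padi4, Chad and Npy1r. The other 4, Prap1, Krt6b, Vegfd and Xdh, were not, and the last 3 fall outside the naming rule and were chosen after their values were seen. Of 169 genes called Absent on all 5 other vagina arrays, 21 (12.4%) were called Present on it. The chips differ in probes, so levels were not compared.

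The rise of ciliated-cell genes in the DES oviduct was weighed against a larger share of all epithelium. That would raise simple epithelium genes by as much. On each DES array the mean cilia change exceeded the mean simple-epithelium change, by 1.43 at the least, against 0.182 at most on an oil array (log2). Changes are taken from the oil mean, so the oil differences balance out by construction and show only the spread between oil arrays. The excess restates list shifts already seen and is not a separate test. A scan-day shift common to both groups cancels, since DES and oil oviduct have equal numbers of arrays from each day. By that design it cannot be the whole cause. The smaller of the medians within a scan day was 2.27, with a lone array per group on the second day. Of 16 cilia genes, 15 had every DES array above every oil array, where chance gives 5% per gene in this direction for 3 against 3. These genes are not independent of each other and were already seen to rise, so the count is no further test. More ciliated cells, or earlier expression per cell, are consistent with these values and stay open as hypotheses.

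The lower oocyte genes in the DES oviduct were weighed against ovarian tissue carried over unevenly. Among the 3 oil oviduct arrays, 11 of 12 list members other than Dppa3 were highest on array 2, the array with most Dppa3, against 38.7% of all genes (Fisher's exact test, p = 0.000225). Fisher's test takes genes as independent, while these may rise together on 1 array. Its p-value does not measure the spread between samples and cannot decide on carry-over. Of the 13 genes on that list, 1 is also on another list. Tex15, which is not on the ovary and oocyte list, was lower with DES in all 3 organs. By the same balance of scan days, a day shift common to both groups cannot be the whole cause. Both medians within a scan day were at or below -0.77. Carry-over is a candidate explanation, and a DES effect on ovary or germ cells stays open and untested.

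Skeletal muscle genes were high on oil uterus array 3 and oil oviduct arrays 3 and 1, where 5 fibre genes reached 117%, 80.4% and 42.8% of their oil vagina mean. If vagina RNA were the source, vagina genes such as Krt15 and Hoxd13 would be as high, but they stood at 4.42%, 9.2% and 6.76%. Myh3 stood at 351, 261 and 78.4 on these arrays, against 470.2, 1445.7 and 2310.2 on oil vagina arrays 1, 2 and 3. Muscle from another site of the dissection may be the source, which was not tested.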

How the results depend on the processing

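The tests within the first scan day, without 2 oviduct arrays with conflicting records and without 3 oil arrays with skeletal muscle transcripts were chosen only after the results were seen.

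All counts stayed within 1.5 times of the reported ones under quantile normalization, pseudocounts of 1 and 100, other filters on calls, the value table and no variance trend. In the settings below the cause was not tested unless one is given. Values follow the order oviduct, uterus, vagina and average for DES against oil; oil oviduct and uterus, oil uterus and vagina, oil oviduct and vagina; the same pairs in DES; and the test between organs.

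With the scan day as a block the counts were 2560, 2676, 880 and 4584; 772, 1363 and 1385; 1439, 534 and 1484; and 765. With the replicate number as a block they were 2455, 2592, 775 and 4436; 686, 1288 and 1337; 1377, 480 and 1340; and 722. These blocks take up variance between scan days. With treatment and replicate number together as a random block (correlation 0.373) the average gave 1496 and the test between organs 795. The oil pairs then gave 771, 1383 and 1415, and the DES pairs 1451, 537 and 1421. With array weights the oviduct gave 1968, the uterus 2540, oil oviduct against uterus 617, oil uterus against vagina 1004, DES oviduct against uterus 1317 and the test between organs 542.

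With only the groups compared, the vagina gave 158, the oil pairs 162, 391 and 426, and DES uterus against vagina 179; this uses fewer arrays. It cannot give another value for the average or the test between organs. Within the first scan day the vagina, with 1 DES array, gave 649, oil oviduct against uterus 587, oil uterus against vagina 965 and DES oviduct against uterus 1059. Without the 2 oviduct arrays with conflicting records the oviduct gave 813, oil oviduct against uterus 145 and the test between organs 169. Without the 3 oil arrays with skeletal muscle transcripts these were 463, 49 and 99, and oil oviduct against vagina gave 263. Both leave fewer arrays, the latter 1 of oil oviduct.

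Leaving out each array in turn gave 817 to 1068 for oviduct, 933 to 1287 for uterus, 146 to 370 for vagina and 2246 to 2962 for the average. For the oil pairs it gave 133 to 220, 389 to 515 and 471 to 557, for the DES pairs 473 to 602, 105 to 208 and 429 to 769, and for the test between organs 181 to 332. Where 1 array was left in a group, it was assumed to vary like the other groups.

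Over the 10 contrasts 130 list tests passed, 122 to 134 when an array was left out, and 56 with an estimated correlation. Of the named genes past the threshold, those kept whichever array was left out were 81 of 101 in oviduct, 87 of 98 in uterus, 28 of 61 in vagina and 116 of 131 on average. All 879 named-gene results past the threshold stayed past it with the scan day as a block, and 376 of the 715 others passed with it. Of the 879, 25 were lost with treatment and replicate number together as a random block and 58 within the first scan day. With only the groups compared 104 were lost (644 kept, the average not being run). Without the 2 oviduct arrays with conflicting records 75 were lost, and without the 3 oil arrays with skeletal muscle transcripts 160. Each of the other settings on all arrays lost at most 43. For 2 list tests the sign of the shift turned. Skeletal muscle in uterus within scan day 1 had a signed minus log10 adjusted p of 0.0505 (adjusted p = 0.890). Cholesterol and fatty acid synthesis, DES effect of vagina minus uterus, without DES vagina array 3 had 0.00786 (adjusted p = 0.982), in a range from -4.13 to 0.00786 over the arrays left out. Neither was past the threshold then, and the cause was not tested. Signal near background limits genes called Absent, whose folds are lower bounds.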

Other observations

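The tests of the scanner record were chosen only after the result was seen, and the other splits of the arrays were planned.

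Single genes of mast cells and of innate defence changed under DES, and neither group has a fixed list of its own. A broader macrophage and leukocyte list was tested. Its DES shift passed in vagina, though not without DES vagina array 2, and its DES effect differed between vagina and oviduct. The mast-cell protease genes Cma1 and Tpsb2 fell in oviduct, as did Cpa3 (211 ± 42.9 against 708 ± 260.1, at least 2.92-fold lower, adjusted p = 0.00262). In uterus Tpsb2 (76.2 ± 33.6 against 439 ± 93.3, at least 4.45-fold lower, adjusted p = 2.2e-05) fell, and in vagina Cma1 (92.5 ± 32 against 359 ± 93.6, at least 3.12-fold lower, adjusted p = 0.0106), though not without either of 2 arrays (highest adjusted p = 0.165, without DES vagina array 3). In vagina Tpsb2 was lower by at least 1.29-fold, not past the threshold. Its falls are lower bounds in each organ, so the organs cannot be ranked. In uterus the defence genes S100a8 (992 ± 188 against 211 ± 8.1, log2 change 2.06, adjusted p = 7.85e-05), S100a9 (953 ± 381 against 275 ± 34.8, log2 change 1.62, adjusted p = 0.000722) and Cd14 (1751 ± 362 against 528 ± 184, log2 change 1.71, adjusted p = 7.94e-05) rose. S100a8 and S100a9 encode the calprotectin subunits, and Cd14 a receptor for bacterial lipopolysaccharide. The same signs held for S100a8 in vagina (552 ± 245 against 177 ± 62, adjusted p = 0.0130, but 0.259 without DES vagina array 3) and for Cd14 in oviduct (1228 ± 217 against 578 ± 55.5, adjusted p = 0.00702). The myeloid genes Lyz2 (-0.58) and Mrc1 (-0.65) were on the lower side in the DES oviduct, not past the threshold. No source of the mast-cell change was tested.

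Hdc, the gene for the enzyme that makes histamine, rose in oviduct and fell in vagina under DES. In oil it stood at 569, 261 and 594 on the oviduct arrays and at 947 ± 325 in vagina (SD, n = 3), and was called Absent in uterus. Under DES it stood at 2391 ± 668 in oviduct (SD, n = 3) and was called Absent in uterus and vagina. Hdc in oviduct did not follow the mast-cell proteases, which fell there. The germ-cell gene Ddx4 rose in the DES uterus (200.2 ± 89.1 against 20.9 ± 16.5, at least 3.47-fold higher, adjusted p = 0.00150). Its DES effect differed between organs (adjusted p = 0.00869).

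The scanner's record for DES oviduct array 3 names the vagina as its sample. On 570 genes that differ between DES oviduct and vagina without it, the array lay at a median position of 0.926 on a scale from vagina (0) to oviduct (1). That value argues against an array wholly of vagina RNA. A median over genes cannot rule out a smaller share of it.

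In the oviduct, 1 of the 10 splits of the 6 DES and oil arrays, the real one, gave 1300 probe sets, and the highest of the other splits gave 0. The real and highest other counts were 1412 and 0 in the uterus. They were 246 and 6 for oil oviduct against uterus, 627 and 0 for oil uterus against vagina, 659 and 1 for oil oviduct against vagina, and 703 and 0 for DES oviduct against uterus. With 10 splits the share is never under 0.05. For the average over the organs, 1 of 100 splits of the arrays within organs reached 2860, the real one. The highest other split gave 1517 and put all 6 arrays of the second scan day in the DES group. Its grouping goes with the scan day, but whether the scan day caused its count was not tested. With the scan day as a block the real count was 4584. The next highest gave 294. These splits take the arrays as independent, while arrays of the same treatment and number were correlated across organs (0.373, scan day included). Moving these arrays together as sets makes 10 splits, too few for a share under 0.05. This test was added after the results were seen. The real split of the sets gave 2860 and the highest other 2165, with all 6 arrays of the second scan day in the DES group. The other set splits with these 6 arrays in 1 group gave 0, 0 and 1165. Placing them together thus did not always raise the count.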
